A study of Escherichia coli with 24 samples.

How the data were processed

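Transcript levels were measured in 24 samples of *Escherichia coli* on the Affymetrix E. coli sense genome array, with mRNA-enriched RNA labelled directly with biotin. The values deposited by the authors are 1 intensity per probe set and array on a linear scale, made with GCRMA per the submitters' processing notes. GCRMA corrects for background, scales arrays to each other and summarises the probes of a set. Its version and settings are not given in the sources used here. Scaling of this kind makes the spread of values alike between arrays, so a change of total mRNA cannot be seen. The number of arrays limits the precision of each value.

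The arrays held 7312 probe sets, of which 22 were controls and 2761 were intergenic by their identifier and paired with no gene. The 4189 probe sets paired with exactly 1 gene (4127 genes, 57 of them with more than 1 probe set) were tested, and 4140 of them shared an Entrez identifier with a gene of the RefSeq annotation of assembly ASM584v2. Of these 4189, 106 carried an intergenic identifier. The 27 probe sets paired with several genes and the other probe sets without a gene were left out of the gene counts. The 90th percentile of the 2761 intergenic probe sets was taken as the background level of an array. A gene is said to lie at or near background level when its mean was below it in each group compared.

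Samples were grouped by strain and treatment from the labels, with 3 arrays in each of 8 groups. A pair of arrays was taken as near-identical when the SD of their log2 difference over 848 bright probe sets was under 0.3. This held for mutS mock replicates 1 and 2 (0.284) and mutS cisplatin replicates 2 and 3 (0.188), while the next pair of a group, dam cisplatin replicates 2 and 3, gave 0.471 and the median pair of a group 1.13. Each near-identical pair was averaged, which departs from the plan of 3 replicates per group and leaves the mutS groups with n = 2. Whether the other arrays stem from separate cultures is not stated, so the p-values measure the spread between arrays.

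Values were transformed as log2(intensity + 1), which understates changes of genes of low intensity. One limma fit of 8 group means (R 4.3.3, limma 3.58.1, lmFit and eBayes) on 22 columns had 14 residual and 1.89 prior degrees of freedom. From it came 11 contrasts: cisplatin against mock in each of 4 strains, dam, mutS and dam mutS against WT and dam mutS against dam in mock, and the differences of response between dam and WT, mutS and WT, and dam mutS and dam. The p-values were two-sided and adjusted by the Benjamini-Hochberg method within a contrast, and a gene was called at an adjusted p under 0.05. The SE is that of the fit, so it is shared by comparisons with the same group sizes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

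Gene lists written from general knowledge of the organism, 30 in number, were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a contrast, with each gene represented by its probe set of highest mean. They covered the SOS regulon, mismatch repair, the dam operon, recombination and replication restart, excision repair outside the SOS regulon, DNA replication, ribonucleotide reduction, heat shock, cold shock, envelope stress, oxidative stress, thiol and glutathione, metal efflux and uptake, iron acquisition, flagella and chemotaxis, acid and general stress, ribosomal proteins, aerobic respiration and ATP synthase, the citric acid cycle and glyoxylate shunt, anaerobic respiration, purine, pyrimidine and amino acid biosynthesis, sulfate assimilation and cysteine, maltose and carbon transport, tryptophanase and indole, the e14, Qin and Rac, and DLP12 and CP4-57 prophages, and nucleoid and phase variation. A list is said to rank higher or lower when its members lie above or below other genes in the contrast. The same lists were tested with the correlation estimated for each list and with fry.

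The named genes were, per comparison, the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between the groups, for an interaction the 6 largest called differences of each sign, dam and mutS, the 4 members of each list with the smallest p and any member needed for a count of 5 or fewer, and across strains the 8 genes called in the most strains in each direction. Other genes and the ribosomal RNA probe sets were chosen after their values were seen. These rules, the lists, the tests and the alternatives not marked otherwise were set before the data were examined.

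The alternatives were a pseudocount of 16, all probe sets that are not controls, leaving out the dimmest 25% of gene probe sets, an intensity trend with robust eBayes, a fit of the arrays of the groups compared alone, the replicate number as a block, array weights, centring each array on the median of its brighter gene probe sets, those above the median in mean level, and leaving out each array in turn. Keeping all 24 arrays separate, averaging dam cisplatin replicates 2 and 3 as well, and testing only genes above the intergenic level in at least 1 group were chosen after seeing the data. Where leaving out an array leaves a mutS group with 1 value, that value is assumed to vary like the other groups.

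The model was tested on simulated data with planted changes in dam after cisplatin, over 5 runs of 4189 genes. It recovered 46.8% of changes of 1 in log2, 82.8% of 2, 90.4% of 3 and 99.2% of 4, with 5.11% false among 841 calls. A planted list was found in 5 of 5 runs, with 0 other lists called. The changed genes were drawn at random from all gene probe sets, each with its own spread, and falls were planted even where the floor leaves no room. Only 10.6 to 24.2% of gene probe sets exceeded the intergenic level of an array. The recovery thus describes mostly genes near background, not bright genes with a larger spread. For dam against WT in mock, recA differed by 3.99 in log2 (SE 0.675) and did not pass. The simulated genes varied independently of each other. Neither the share of false calls nor the list result therefore covers genes that vary together.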

Results

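Transcript levels were measured in *Escherichia coli* on 24 Affymetrix sense genome arrays that fell into 8 groups of 3. The groups crossed 4 strains with 2 treatments. The strains were the wild type (WT), a dam mutant lacking the methyltransferase that marks adenines in GATC sites, a mutS mutant lacking the protein that recognises mismatched bases, and a dam mutS mutant lacking both. Cells were exposed to cisplatin, a platinum drug that crosslinks neighbouring bases in DNA, at 150 µM for 2 h at 37 °C, or were mock treated, and then recovered in rich medium for 90 min before RNA isolation. The median intensity of an array lay between 9.26 and 10.5 and its maximum between 15937 and 26606. Intergenic probe sets with no gene served as the background, and their 90th percentile lay between 27.3 and 45.8 per array. Between 442 and 1012 of the 4189 gene probe sets (10.6 to 24.2%) exceeded it on an array. The number of arrays limited the precision of each value. A pair of arrays in each mutS group was nearly identical and was averaged, so that the mutS groups held n = 2 and the other groups n = 3. The probe sets for dam and mutS lay near the floor in all 8 groups, with geometric means of 6.01 to 7.32 for dam and 7.92 to 11.1 for mutS, WT included, and so could not check the strain labels. Fold changes come from log2(intensity + 1), errors are SE of the log2 change, and levels are geometric means of the group. A fold or log2 change with a group below the background depends on the background correction.

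The first question was which transcripts cisplatin changed in WT cells. It raised genes of the SOS response, the DNA damage regulon repressed by LexA. recA, which encodes the recombinase that triggers LexA cleavage, was 42.0-fold higher than in mock (log2 5.39 ± 0.675, n = 3 and 3, adjusted p = 0.000496), at 1290 against 29.8. yebG, dinI and sulA, the last of which encodes an inhibitor of cell division, were 22.4-fold, 21.5-fold and 12-fold higher (SE 0.661, 0.497 and 0.393 in log2, adjusted p = 0.00316 or lower). ymfJ (b1144) and ymfL (b1147), genes of the cryptic e14 prophage, were 27.6-fold and 9.85-fold higher (SE 0.489 and 0.341, both with adjusted p = 9.78e-05). yebF, which encodes an exported protein and neighbours yebG in the ASM584v2 annotation, was 7.95-fold higher (SE 0.447, adjusted p = 0.00321). murE, a ligase gene of peptidoglycan synthesis, fell by 2.49 in log2 (SE 0.482, adjusted p = 0.0489), from 54.0 to 8.77. In each of these genes the 3 arrays of one group lay wholly above the 3 of the other. The mock levels of ymfJ, ymfL, yebG and sulA (11.1, 10.4, 11.5 and 18.8) lay below the intergenic level of 28.5, and murE after cisplatin lay below that of its group. Set against these levels the changes were 11.3-fold, 3.81-fold, 9.48-fold, 8.08-fold and 1.78-fold. The mock level of recA lay just above 28.5. WT mock replicates 1 and 3, at 25.1 and 13.1, lay below their own intergenic levels of 28.2 and 30.2, so its fold depends on the background too.

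By list, 4 of the 31 SOS genes measured in WT rose, and 7 did when adjusted over the list alone, with lexA, umuD and recN added (camera adjusted p = 4.51e-12, adjusted p = 0.0733 with an estimated correlation). Of 20 e14 genes 2 rose, and 5 when adjusted over the list alone (adjusted p = 1.33e-10, adjusted p = 0.0365 with an estimated correlation). The ribosomal protein genes measured, 35 of the 54 listed, had positive changes in 35 of 35 with a median log2 of 1.57. The list ranked above other genes (adjusted p = 1.94e-37, adjusted p = 0.0733 with an estimated correlation). 0 of them passed over all genes under limma, and rpsA, rpmF and rpmJ passed when adjusted over the list alone. The flagella and chemotaxis list ranked lower (adjusted p = 3.04e-10, adjusted p = 0.519 with an estimated correlation), with 0 genes of 51 over all genes and 4 adjusted over the list alone, fliA, fliC, flgN and cheY. The lists of acid and general stress, of maltose and carbon transport and of the citric acid cycle also ranked lower (adjusted p = 2.98e-05, 0.00199 and 0.00579), with 0 genes called and adjusted p = 0.67, 0.67 and 0.897 with an estimated correlation. Without WT mock replicate 2 these last lists gave 0.211, 0.165 and 0.541, and the citric acid cycle list also gave 0.0583 without WT cisplatin replicate 1 and 0.196 without replicate 3.

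In total 7 gene probe sets were higher and 1 lower in WT under limma, with 119 at an unadjusted p under 0.05. The 2 groups did not overlap in 404 gene probe sets (9.64%, where chance gives 10%). The count was 1 when only the 6 WT arrays entered the fit and 72 with array weights, and murE kept its call only without WT mock replicate 1, its adjusted p reaching 0.294 without WT mock replicate 3.

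**Figure D1:**
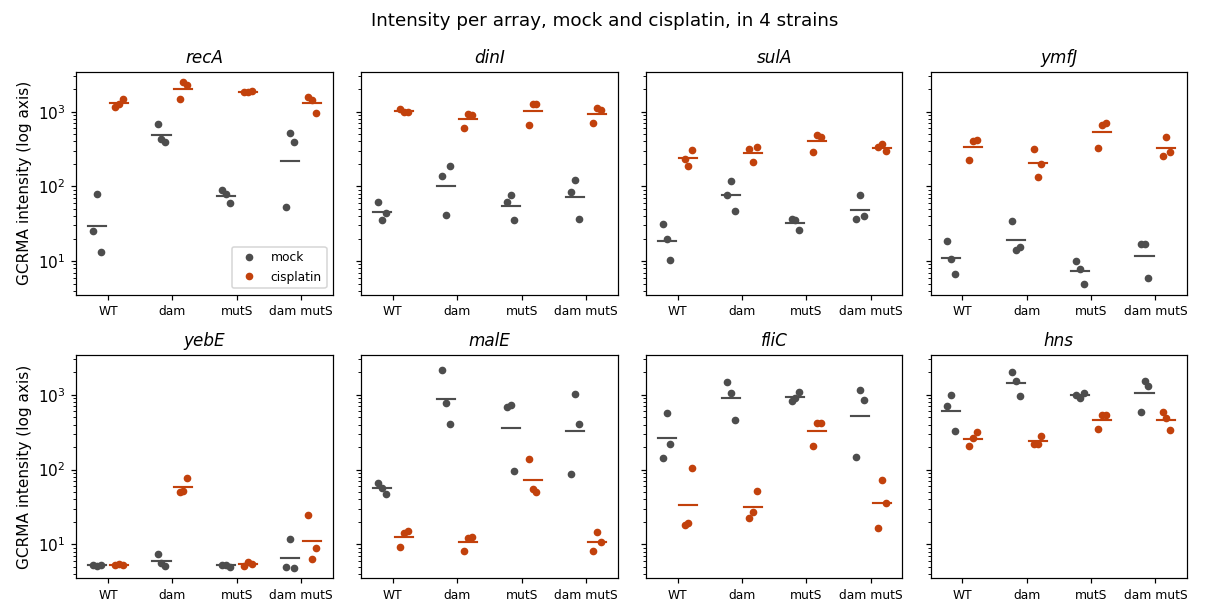
GCRMA intensity on a log axis for 8 genes in each strain, with 1 point per array, mock in grey and cisplatin in orange, and a line at the geometric mean of the 3 arrays. The cisplatin arrays lie above the mock arrays for recA, dinI, sulA and ymfJ in each strain, with geometric means for recA of 1290 against 29.8 in WT and 2040 against 490 in dam.

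The same question was asked of the dam mutant, in which more genes passed than in WT. DNA repair and prophage genes were again among those that rose. ymfJ was 9.99-fold higher (log2 3.32 ± 0.489, n = 3 and 3, adjusted p = 0.00122), recX, whose product restrains RecA, 9.58-fold (SE 0.605, adjusted p = 0.00578), dinI 7.67-fold (SE 0.497, adjusted p = 0.0031), and uvrB and uvrA, which encode damage recognition subunits of nucleotide excision repair, 7.11-fold and 5.27-fold (SE 0.522 and 0.404, adjusted p = 0.00555 and 0.0031). deaD, an RNA helicase gene of the cold shock list, was 9.56-fold higher (SE 0.478, adjusted p = 0.00122), reaching 784, and yhcN and yebE were 10.2-fold and 8.5-fold higher (SE 0.655 and 0.358, adjusted p = 0.00724 and 0.000455). ndh, which encodes the NADH dehydrogenase that does not pump protons, was 6.69-fold higher (SE 0.701, adjusted p = 0.0385). recA itself stood at 2040 against 490, a 4.15-fold difference that did not pass (log2 2.05 ± 0.675, adjusted p = 0.123), and yebG gave 5.31-fold (adjusted p = 0.0531). In mock ymfJ, recX, uvrB, uvrA, yhcN, yebE and ndh lay below the intergenic level of 33.3, against which they were 5.95-fold, 1.87-fold, 6.17-fold, 1.13-fold, 3.36-fold, 1.74-fold and 2.91-fold higher. Of the 51 named calls in dam 30 had 1 group below the intergenic level and 8 both.

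The genes that fell in dam included some of sugar uptake, motility and catabolism. malE and lamB, which encode the periplasmic binding protein and outer membrane porin for maltose, fell by 6.21 and 5.45 in log2 (SE 0.805 and 1.05, adjusted p = 0.000891 and 0.00672), malE from 873 to 10.8. glpK, the glycerol kinase gene, and tnaA, the tryptophanase gene, fell by 5.52 and 5.51 (SE 1.19 and 1.15, adjusted p = 0.0138 and 0.0113). fliC, which encodes flagellin, fell by 4.79 (SE 0.823, adjusted p = 0.00334) and flgF, a flagellar rod gene, by 4.48 (SE 1.09, adjusted p = 0.0296). mdh, the malate dehydrogenase gene, and grcA, which encodes a spare glycyl radical domain for pyruvate formate-lyase, fell by 4.54 and 4.45 (SE 0.755 and 0.613, adjusted p = 0.00296 and 0.00105). Genes of chromosome packaging fell as well, hupB for the HU protein 8.86-fold (SE 0.553, adjusted p = 0.004) and hns, for the silencing protein H-NS, 6.01-fold (SE 0.405, adjusted p = 0.00193). After cisplatin malE, lamB, glpK, tnaA, fliC and flgF lay below the intergenic level of 33.1. Against that level they fell by 4.68, 3.46, 4.15, 4.22, 4.73 and 3.22 in log2, which changes their order.

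By list, 19 of 51 flagella and chemotaxis genes fell in dam, and 34 when adjusted over the list alone (camera adjusted p = 1.13e-25, adjusted p = 0.0952 with an estimated correlation). Of 35 maltose and carbon transport genes 12 fell, among them ptsG of the glucose phosphotransferase system and rbsB of ribose uptake. When adjusted over the list alone 21 fell and 1, araA of arabinose breakdown, rose (adjusted p = 1.95e-11, adjusted p = 0.0952 with an estimated correlation). The list of 3 tryptophanase genes fell, with tnaA over all genes and 3 adjusted over the list alone (adjusted p = 0.00186, adjusted p = 0.152 with an estimated correlation). Of 33 anaerobic respiration genes 4 fell, frdA and frdB of fumarate reductase, pflB and ansB. When adjusted over the list alone 6 fell and fnr, the regulator of anaerobic growth, rose (adjusted p = 0.000585, adjusted p = 0.104 with an estimated correlation). The nucleoid list fell with 4 of 11 genes, dps, hns, hupA and hupB, and the same 4 when adjusted over the list alone. There fis, for a growth phase regulator, rose (adjusted p = 0.00535, adjusted p = 0.242 with an estimated correlation). The citric acid cycle list ranked lower with 1 of 17 genes, mdh, and 2 adjusted over the list alone (adjusted p = 0.000108, adjusted p = 0.452 with an estimated correlation). Acid and general stress ranked lower with 3 of 29, dps, elaB and uspA, and 4 adjusted over the list alone (adjusted p = 0.0101, adjusted p = 0.653 with an estimated correlation). Aerobic respiration ranked lower (adjusted p = 0.000111, adjusted p = 0.474 with an estimated correlation), with 5 genes of 30 lower adjusted over the list alone. Its 1 member called over all genes, ndh, rose.

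SOS genes rose in 7 of 31 in dam, and in 16 adjusted over the list alone, uvrD, ruvA and ruvB included (adjusted p = 6.68e-10, adjusted p = 0.0952 with an estimated correlation). In the DNA replication list 7 of 21 rose and 2, hupA and hupB, fell, with 9 higher and 2 lower adjusted over the list alone (adjusted p = 0.00054, adjusted p = 0.104 with an estimated correlation). The risers included gyrA and gyrB, the gyrase genes, with 6.55-fold and 4.18-fold (SE 0.394 and 0.305, adjusted p = 0.00122 for both), gyrB 3.11-fold against the intergenic level, below which its mock arrays lay. Ribonucleotide reduction ranked higher with nrdA called and 3 of 12 adjusted over the list alone (adjusted p = 0.00374, adjusted p = 0.0952 with an estimated correlation). The e14 list rose with 3 of 20 and 5 adjusted over the list alone (adjusted p = 0.000115, adjusted p = 0.104 with an estimated correlation). Sulfate assimilation ranked higher with sbp and 4 of 24 adjusted over the list alone (adjusted p = 0.00593, adjusted p = 0.212 with an estimated correlation). Beside these changes, 3 of the 18 ribosomal RNA probe sets rose, rrlH 5.92-fold, rrlC 4.6-fold and rrsH 3.33-fold (adjusted p = 0.0457, 0.0138 and 0.0407). The median log2 over the 6 probe sets for 23S rRNA was 2.10, against 0.0604 in WT, -1.02 in mutS and 0.168 in dam mutS. In these 3 strains 0 of the 18 passed under limma (0, 5 and 4 at an unadjusted p under 0.05, all of them falls). Those for 5S rRNA lay between -0.0774 (rrfC) and 0.226 (rrfF) in dam. The RNA was enriched for mRNA, so these values also depend on how much ribosomal RNA was left, which was not tested.

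In total 73 gene probe sets were higher and 85 lower in dam, 42 of them (35 higher, 7 lower) below the intergenic level in both groups. Of all gene probe sets 656 had an unadjusted p under 0.05. The groups did not overlap in 873 (20.8%, where chance gives 10%). The count was 52 with the 6 dam arrays alone, 304 with array weights and 104 with dam cisplatin replicates 2 and 3 averaged, an alternative chosen after seeing the data. It was 91 and 92 without dam mock replicate 1 or 2, and 99 without dam cisplatin replicate 2 or 3. Of the 51 named calls 33 held without each array in turn. Those of flgF and ndh were lost without 5 of the 6 arrays (adjusted p up to 0.12 and 0.138), that of glpK without dam mock replicates 1 and 2 (0.0619 and 0.0556) and that of tnaA without dam mock replicate 2 (0.06). The calls of elaB, pflB, frdB, nrdA, uspA and hupA were each lost without at least 4 of the 6 arrays (adjusted p up to 0.206, 0.163, 0.187, 0.1, 0.13 and 0.113) and that of dps without dam mock replicate 1 (0.0653). The aerobic respiration list gave 0.194 without dam mock replicate 2. Without dam cisplatin replicate 1 ribonucleotide reduction gave 0.0565, acid and general stress 0.0548 and sulfate assimilation 0.0765 (0.0697 without dam mock replicate 1).

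In the mutS mutant cisplatin raised genes of the SOS response and of e14. ymfJ was 61.4-fold higher (log2 5.94 ± 0.599, n = 2 and 2, adjusted p = 0.000136), and ymfL and ymfT, also of e14, 12.1-fold and 3.91-fold (SE 0.418 and 0.316, adjusted p = 0.000463 and 0.00664). yebG, recA, dinI and sulA were 32.7-fold, 25.7-fold, 18.3-fold and 11.8-fold higher (SE 0.809, 0.827, 0.608 and 0.481, adjusted p = 0.015 or lower), recA at 1850 against 70.9. yebF was 7.03-fold higher (SE 0.547, adjusted p = 0.0385). ydfE, a pseudogene of the Qin prophage, was 1.52-fold higher at a level near background (SE 0.119, adjusted p = 0.0428). fbaB, which encodes a fructose-bisphosphate aldolase, fell by 1.45 in log2 and yciG by 0.88 (SE 0.229 and 0.15, adjusted p = 0.00664 and 0.011). The mock levels of ymfJ, ymfL, ymfT and yebG (6.72, 9.92, 16.5 and 13.1) lay below the intergenic level of 29.7, against which they were 15.4-fold, 4.32-fold, 2.23-fold and 15.1-fold higher. fbaB lay below that of 31.8 after cisplatin, against which it was 1.1-fold lower, and yciG was below in both groups.

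By list, 4 of 31 SOS genes rose in mutS, and 9 adjusted over the list alone (camera adjusted p = 1.6e-15, adjusted p = 0.0333 with an estimated correlation). Of 20 e14 genes 3 rose, and 4 adjusted over the list alone (adjusted p = 2.39e-13, adjusted p = 0.0126 with an estimated correlation). The tryptophanase list ranked higher with 0 genes over all genes and tnaC, its leader peptide gene, adjusted over the list alone (adjusted p = 0.00145, adjusted p = 0.327 with an estimated correlation). Ribosomal protein genes ranked higher with a median log2 of 0.94 and 0 genes on either count (adjusted p = 4.26e-13, adjusted p = 0.566 with an estimated correlation). Qin and Rac prophage genes ranked higher with ydfE, or 2 of 32 adjusted over the list alone (adjusted p = 0.0117, adjusted p = 0.566 with an estimated correlation). Flagella and chemotaxis ranked lower with 0 genes, or cheA and cheY adjusted over the list alone (adjusted p = 1.07e-09, adjusted p = 0.566 with an estimated correlation). Acid and general stress and the citric acid cycle ranked lower with 0 genes on either count (adjusted p = 6.98e-06 and 0.00862, adjusted p = 0.599 and 0.966 with an estimated correlation). Of the 18 ribosomal RNA probe sets 0 passed in mutS under limma (adjusted p = 0.982 or higher, 5 at an unadjusted p under 0.05). The signs divided with 11 below 0 in mutS and 12 in dam mutS, and rrlD, rrlE and rrsA gave log2 changes of -3.82, -2.48 and -2.09 in mutS (SE 1.47, 1.03 and 0.744).

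In total 10 gene probe sets were higher and 2 lower in mutS under limma, with 193 at an unadjusted p under 0.05. With the pairs averaged the groups did not overlap in 1350 (32.2%, where chance gives 33.3% for n = 2 and 2). The count was 0 with the mutS arrays alone, 19 with all 24 arrays kept separate, an alternative chosen after seeing the data, and 23 without mutS cisplatin replicate 1. Without mutS mock replicate 3, which leaves 1 independent mock value assumed to vary like the other groups, the calls of recA, yebF, ymfT and fbaB were lost (adjusted p = 0.11, 0.133, 0.0844 and 0.076). The lists of stress, ribosomal protein, citric acid cycle and Qin and Rac genes then gave 0.833, 0.139, 0.88 and 0.955. Without mutS cisplatin replicate 1 recA gave 0.0685, yebF 0.119 and the stress list 0.11. The call of yciG was lost without mutS mock replicates 2 and 3 (adjusted p = 0.128 and 0.111) and that of ydfE without 4 of the 6 arrays (up to 0.31). The Qin and Rac list gave 0.398 without mutS cisplatin replicate 1.

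In the dam mutS mutant, which asks what the loss of MutS changes in cells without Dam, cisplatin again raised SOS and prophage genes. ymfJ was 24.8-fold higher (log2 4.64 ± 0.489, n = 3 and 3, adjusted p = 6.35e-05), ymfL 9.46-fold and xisE, the e14 excisionase gene, 9.99-fold (SE 0.341 and 0.716, adjusted p = 6.35e-05 and 0.0237). dinI, yebG and sulA were 12.8-fold, 10.9-fold and 6.67-fold higher (SE 0.497, 0.661 and 0.393, adjusted p = 0.0106 or lower). argW, an arginine tRNA gene, was 16.1-fold higher (SE 0.759, adjusted p = 0.0103). sodA, the manganese superoxide dismutase gene, and tsuB, a gene of thiosulfate uptake, were 9.93-fold and 7.46-fold higher (SE 0.764 and 0.6, adjusted p = 0.0393 and 0.0187). recA stood at 1290 against 222 (mock arrays of 53.0, 524 and 388), a 5.81-fold difference that did not pass (SE 0.675, adjusted p = 0.076). The falls were led by tnaA, malE and lamB, by 4.89, 4.82 and 4.47 in log2 (SE 1.15, 0.805 and 1.05, adjusted p = 0.0417, 0.00434 and 0.0417). The flagellar genes fliC, flgB, flgC, fliA (for the sigma factor of late flagellar genes) and flgE (for the hook) fell by 3.86, 3.57, 3.50, 3.43 and 3.21 (SE 0.823, 0.652, 0.631, 0.555 and 0.732, adjusted p = 0.037 or lower). In mock ymfJ, ymfL, xisE, argW, sodA and tsuB lay below the intergenic level of 30.9, against which they were 10.1-fold, 3.17-fold, 5.42-fold, 12.1-fold, 3.01-fold and 3.06-fold higher. After cisplatin tnaA, malE, lamB, flgB, flgC, fliA and flgE lay below that of 35.0, against which they fell by 3.68, 3.21, 1.93, 2.16, 3.02, 1.98 and 2.03 in log2. This changes the order of the falls, since fliC, which was not below that level, fell by 3.86.

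By list, 9 of 51 flagella and chemotaxis genes fell in dam mutS, and 16 adjusted over the list alone (camera adjusted p = 4.47e-14, adjusted p = 0.187 with an estimated correlation). Of 35 maltose and carbon transport genes 2 fell, malE and lamB, or 4 adjusted over the list alone (adjusted p = 5.22e-07, adjusted p = 0.187 with an estimated correlation). The tryptophanase list fell with tnaA, or 2 adjusted over the list alone (adjusted p = 0.0142, adjusted p = 0.219 with an estimated correlation). SOS genes rose in 4 of 31, or 12 adjusted over the list alone (adjusted p = 5.22e-07, adjusted p = 0.187 with an estimated correlation). In the e14 list 5 of 20 rose, or 7 adjusted over the list alone (adjusted p = 4.57e-05, adjusted p = 0.187 with an estimated correlation). Sulfate assimilation rose with 4 of 24, sbp for sulfate binding, cysM for cysteine synthesis, and ssuB and ssuC for sulfonate uptake, all 4 below the intergenic level in both groups. Adjusted over the list alone 8 rose (adjusted p = 2.34e-05, adjusted p = 0.187 with an estimated correlation). sbp was 2.54-fold higher (SE 0.145, adjusted p = 7.04e-05). DNA replication ranked higher with dnaN, gyrB and topA of 21, or 5 adjusted over the list alone (adjusted p = 0.0049, adjusted p = 0.187 with an estimated correlation). Ribonucleotide reduction ranked higher with nrdB, or 2 of 12 adjusted over the list alone (adjusted p = 0.0437, adjusted p = 0.187 with an estimated correlation). Recombination and replication restart ranked higher with 0, or recB adjusted over the list alone (adjusted p = 0.0133, adjusted p = 0.187 with an estimated correlation). Purine and amino acid biosynthesis ranked higher with purF and metK, or 1 of 16 and 3 of 41 adjusted over the list alone (adjusted p = 0.0172 and 0.0133, adjusted p = 0.219 with an estimated correlation for both).

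Prophage genes of DLP12 and CP4-57 ranked lower in dam mutS with yfjH, 1 of 42 on both counts, that is over all genes and adjusted over the list alone (adjusted p = 2.38e-05, adjusted p = 0.187 with an estimated correlation). Anaerobic respiration ranked lower with nirD, a nitrite reductase gene, or 3 of 33 adjusted over the list alone (adjusted p = 0.0133, adjusted p = 0.219 with an estimated correlation). Acid and general stress ranked lower with 0 of 29, or dps and gabD adjusted over the list alone (adjusted p = 0.0049, adjusted p = 0.687 with an estimated correlation). Ribosomal protein genes ranked higher with a median log2 of 0.59 and 0 genes on either count (adjusted p = 0.0117, adjusted p = 0.88 with an estimated correlation). They turned lower without dam mutS mock replicate 1 (0.847). fbaB fell by 1.85 in log2, yfjH by 1.56 and nirD by 1.59 (SE 0.187, 0.175 and 0.233, adjusted p = 0.00133 or lower). fbaB lay below the intergenic level of 35.0 after cisplatin, against which it fell by 0.359, and yfjH and nirD in both groups. These 3 were also higher in the untreated dam mutS cells than in WT, with which they share the mock arrays.

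In total 30 gene probe sets were higher and 40 lower in dam mutS, 37 of them (16 higher, 21 lower) below the intergenic level in both groups. Of all gene probe sets 654 had an unadjusted p under 0.05, and in 539 (12.9%, where chance gives 10%) the groups did not overlap. Dam mutS cisplatin replicate 1 stood nearer to the 3 dam cisplatin arrays (mean SD of the log2 difference 0.973) than to its own group (1.52). Without it 150 were higher and 39 lower, 60 of them among the 70, and the lists of ribonucleotide reduction, purine biosynthesis, recombination, acid stress, tryptophanase, DNA replication and ribosomal protein genes gave adjusted p = 0.403, 0.306, 0.163, 0.213, 0.111, 0.0868 and 0.905. The count was also 154 without dam mutS mock replicate 3, 2 with the 6 dam mutS arrays alone and 39 with array weights. Over all probe sets that are not controls it was 118, probe sets without a gene included. It was 44 among genes above the intergenic level in at least 1 group, an alternative chosen after seeing the data. The split was 40 higher and 31 lower (56.3% higher against 42.9%) with arrays centred on their brighter gene probe sets. Without dam mutS mock replicate 3 the tryptophanase, anaerobic respiration, ribonucleotide reduction, amino acid and purine lists gave 0.175, 0.146, 0.14, 0.0612 and 0.0549. Without mock replicate 2 acid stress gave 0.203 and recombination and ribonucleotide reduction 0.0851. Without mock replicate 1 purine biosynthesis gave 0.107, and without cisplatin replicate 2 amino acid biosynthesis gave 0.128 and anaerobic respiration 0.0583. Of the 38 named calls 25 held without each array. Those of tnaA, lamB, xisE, sodA and flgE were lost without 4 of the 6 arrays (adjusted p up to 0.0958, 0.125, 0.11, 0.133 and 0.113) and that of fliC without 3 (up to 0.0838, without dam mutS mock replicate 2). The calls of gyrB, topA, purF and cysM were each lost without at least 3 of the 6 arrays (up to 0.137, 0.123, 0.116 and 0.105).

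**Figure D2:**
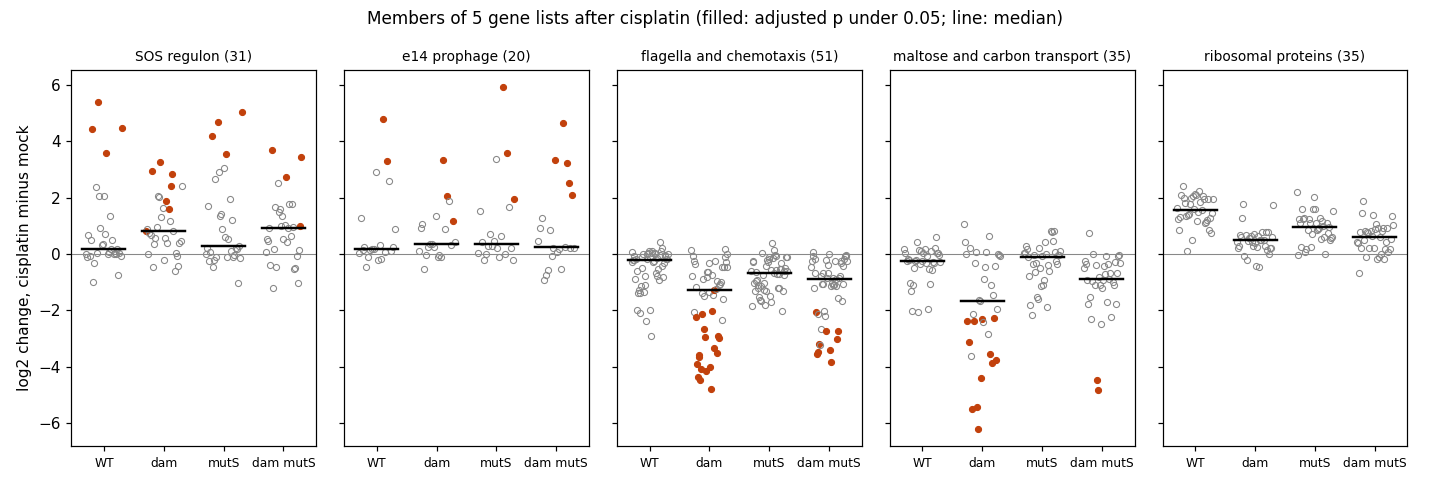
Log2 change after cisplatin, relative to mock, of each measured member of 5 gene lists in each strain, with 1 point per gene, filled where the adjusted p was under 0.05, and a line at the median. The SOS and e14 points that pass lie above 0 in each strain, and 19 of 51 flagella and chemotaxis genes pass below 0 in dam and 9 in dam mutS.

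To ask whether strains respond alike, the called genes were compared between strains. ymfJ, dinI, ymfL, sulA and yebF passed as higher in all 4 strains, with mean log2 changes of 4.67, 3.81, 3.05, 2.94 and 2.62, and yebG passed in 3. The calls of ymfJ, dinI and ymfL held without each array in each strain. That of sulA in dam was lost without dam cisplatin replicate 3 (adjusted p = 0.0567) and that of yebF in mutS and in dam mutS without 2 arrays each (up to 0.133 and 0.0725). recA and deaD passed as higher in 2 strains each, though for recA each cisplatin array lay above each mock array in all 4 strains. fbaB passed as lower in 3 strains, and malE, fliC, lamB, fliA, flgN, flgC and flgB in 2, dam and dam mutS. In WT malE did not pass, at 46.9 to 66.6 in mock and 9.35 to 14.9 after cisplatin. The mean log2 change in dam and dam mutS was between -5.51 (malE) and -3.46 (flgN), and over all 4 strains between -3.67 and -2.60. malE lay below the intergenic level after cisplatin in dam and dam mutS. Against that level fliC fell further in each, so the order depends on the background. No gene passed in opposite directions in any pair of strains. WT and mutS shared 7 risers of 7 and 10, where chance gives 0.0167. dam and dam mutS shared 13 risers of 73 and 30 and 15 fallers of 85 and 40, where chance gives 0.523 and 0.812. WT and dam shared 5 risers (0.122 by chance), WT and dam mutS 6 (0.0501), dam and mutS 5 (0.174), and mutS and dam mutS 6 (0.0716). Across the 4189 gene probe sets, which are not independent replicates, r between log2 changes was 0.628 for WT and mutS, 0.656 for dam and dam mutS, and between 0.267 and 0.407 for the other pairs. The rank correlations were lower, 0.35 for WT and mutS, 0.514 for dam and dam mutS, and between 0.0653 and 0.111 for the other pairs. The r of WT and mutS was 0.347 without mutS mock replicate 3, and that of dam and dam mutS was 0.484 without dam mutS mock replicate 2 and 0.748 without dam mutS mock replicate 1.

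Differences in response were tested as interactions. The response of dam exceeded that of WT in yebE (b1846), by 3.07 in log2 (SE 0.506, adjusted p = 0.0356), and in mgtA (b4242), which encodes a magnesium transporter, by 2.51 (SE 0.405, adjusted p = 0.0356). In dam, yebE went from 6 to 58.5 and mgtA from 10.2 to 63.9. Their other 3 groups lay below the intergenic level, so the sizes depend on the background, and against that level they were 1.74-fold and 1.89-fold higher in dam after cisplatin. In WT yebE stood at 5.26 in mock and 5.35 in cisplatin and mgtA at 9.88 and 10.1. 0 genes passed in the other direction. For recA the difference was -3.34 (SE 0.954, adjusted p = 0.286) and for hupB -3.63 (SE 0.783, adjusted p = 0.0916). It was for gyrB 1.97 (SE 0.431, adjusted p = 0.0976), for malE -4.14 (adjusted p = 0.25) and for fliC -1.86 (adjusted p = 0.76), so these did not pass, and gyrB, malE and fliC had a group below the intergenic level as well.

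By list, flagella and chemotaxis and maltose and carbon transport responded lower in dam than in WT (camera adjusted p = 3.68e-13 and 7.24e-07, adjusted p = 0.371 with an estimated correlation for both). Over all genes 0 of 51 and 0 of 35 passed, and 0 and 8 adjusted over the list alone, the 8 being malE, lamB, malK, malM, galT, ptsG, rbsB and treB. Tryptophanase, anaerobic respiration, aerobic respiration, the citric acid cycle and ribosomal proteins responded lower (adjusted p = 0.0135, 0.0114, 0.00219, 0.0342 and 2.31e-05, adjusted p = 0.371, 0.371, 0.657, 0.705 and 0.657 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone tnaA did. DNA replication responded higher (adjusted p = 0.00279, adjusted p = 0.371 with an estimated correlation), with 0 genes over all genes and 8 higher and 2 lower adjusted over the list alone. At an unadjusted p under 0.05 there were 316 genes. The count of 2 ranged from 0 to 31 over arrays left out. It was 0 without any of 10 of the 12, 1 without dam mock replicate 3, which lost yebE (adjusted p = 0.0509), and 31 without dam cisplatin replicate 1, and was 106 with array weights. The calls of yebE and mgtA were lost without 11 and 10 of the 12 arrays (adjusted p up to 0.14, without dam mock replicate 2). Without dam mock replicate 2 aerobic respiration gave 0.462, the citric acid cycle 0.772 and tryptophanase 0.102 (0.0562 without dam cisplatin replicate 1). The citric acid cycle list also gave 0.182 without WT cisplatin replicate 2, 0.172 and 0.0679 without WT mock replicates 1 and 3 and 0.0938 without dam cisplatin replicate 1. Anaerobic respiration gave 0.0564 without WT mock replicate 3.

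The response of mutS differed from that of WT in 0 genes under limma (lowest adjusted p = 0.201), with 58 at an unadjusted p under 0.05 and 3 called without mutS cisplatin replicate 1. By list, SOS, e14 and tryptophanase genes responded higher (adjusted p = 0.015, 0.0147 and 0.000429, adjusted p = 0.935, 0.935 and 0.395 with an estimated correlation), with 0 genes over all genes and 0 adjusted over the list alone. Without mutS mock replicate 3 SOS gave 0.0906 and e14 0.539. SOS also gave 0.0983 and 0.0994 without WT cisplatin replicates 1 and 2, and e14 0.163 and 0.0935 without WT mock replicate 1 and WT cisplatin replicate 1. The response of dam mutS differed from that of dam in 0 genes under limma (lowest adjusted p = 0.0606, for yfjH, by -1.31 at background level), with 250 at an unadjusted p under 0.05. The count was 47 without dam mutS cisplatin replicate 1, 21 without dam cisplatin replicate 1, 12 without dam mutS mock replicate 3 and 10 without dam mutS mock replicate 2. By list, flagella and chemotaxis, maltose and carbon transport, aerobic respiration, the citric acid cycle and the nucleoid genes responded higher than in dam, and DLP12 and CP4-57 genes lower (adjusted p = 0.00277, 0.0446, 0.000895, 0.0038, 0.0488 and 0.0038, adjusted p = 0.916 with an estimated correlation for each). Over all genes 0 passed and, adjusted over the list alone, hupA and hupB were higher and yfjH lower. Each of these 6 lists lost its call without at least 2 of the 12 arrays. Without dam mutS mock replicate 1 flagella, nucleoid and DLP12 and CP4-57 genes gave 0.434, 0.222 and 0.237. Without dam mock replicate 2 aerobic respiration and the citric acid cycle gave 0.534 and 0.582, and without dam mock replicate 1 maltose and carbon transport gave 0.257.

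**Figure D3:**
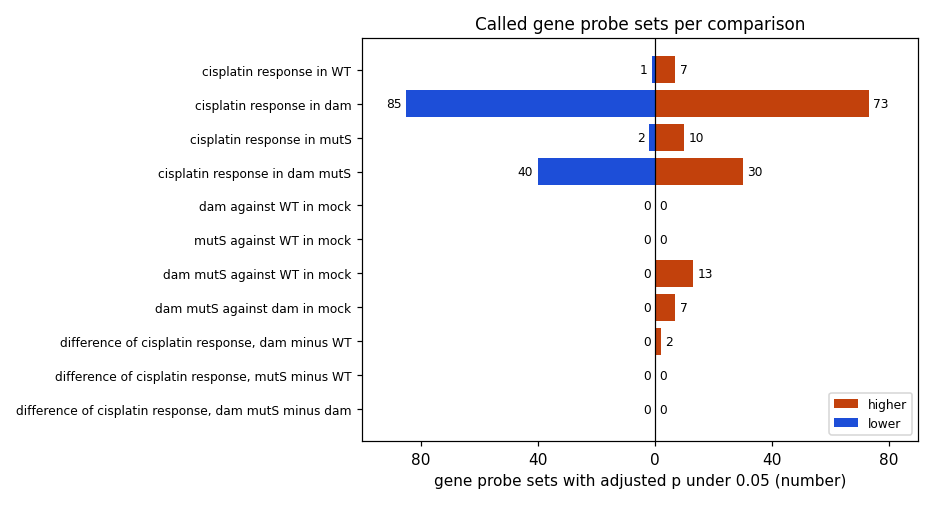
Number of gene probe sets with an adjusted p under 0.05 in each comparison, higher to the right in orange and lower to the left in blue. Cisplatin gave 73 higher and 85 lower in dam, 30 and 40 in dam mutS, 7 and 1 in WT and 10 and 2 in mutS.

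Strains were then compared without the drug, which asks what the mutations change by themselves. The comparisons with WT use the same WT mock arrays as the WT cisplatin response, so these results are not independent. A gene list low in those arrays, such as that of ribosomal proteins might be, would rank higher in each of them. In dam against WT, no gene passed. recA stood at 490 against 29.8 (log2 3.99 ± 0.675, n = 3 and 3, adjusted p = 0.0821), and lexA, yebG and sulA gave 7.53-fold, 9.27-fold and 3.86-fold (SE 0.579, 0.661 and 0.393, adjusted p = 0.0821 for each). lamB, malE and atpE, a subunit gene of ATP synthase, gave 36.3-fold, 15.3-fold and 6.67-fold with the same adjusted p. In each of these genes, recA, lexA, yebG and sulA included, the 3 dam arrays lay wholly above the 3 WT arrays. In WT mock yebG, sulA and lamB lay below the intergenic level of 28.5, against which they gave 3.93-fold, 2.59-fold and 12.7-fold. recA and lexA, at 29.8 and 29.3 in WT mock, lay just above that level. The SOS list did not pass (camera adjusted p = 0.0796, adjusted p = 0.767 with an estimated correlation), with 0 of 31 over all genes and 5 adjusted over the list alone, lexA, recA, recN, sulA and yebG. It gave 0.0199 with arrays centred on their brighter gene probe sets, and 0.0406 without dam mock replicate 2 and up to 0.189, without dam mock replicate 3. Ribosomal protein genes ranked higher, with a median log2 of 2.29, 35 of 35 positive, 0 over all genes and 31 adjusted over the list alone (camera adjusted p = 1.14e-32, adjusted p = 0.335 with an estimated correlation). Flagella and chemotaxis and maltose and carbon transport ranked higher with 0 over all genes and 12 and 10 adjusted over the list alone (adjusted p = 3.7e-15 and 1.63e-07, adjusted p = 0.483 with an estimated correlation for both). Aerobic respiration ranked higher with 0 and 8, atpB, atpD, atpE and atpG among them (adjusted p = 2.44e-09, adjusted p = 0.591 with an estimated correlation). Heat shock, cold shock, anaerobic respiration and nucleoid genes ranked higher and acid and general stress lower (adjusted p = 0.00675, 0.0128, 0.0458, 0.0458 and 0.0294, adjusted p = 0.593, 0.593, 0.593, 0.593 and 0.767 with an estimated correlation). Over all genes 0 of them passed and, adjusted over the list alone, hns and hupB of the nucleoid list were higher. These 5 lists each lost the call without at least 2 arrays. Heat shock reached 0.113 without dam mock replicate 3, and cold shock, anaerobic respiration and nucleoid genes 0.283 without WT mock replicate 3. Acid and general stress reached 0.782 without WT mock replicate 2, and aerobic respiration gave 0.0546 without dam mock replicate 2. In total 0 genes passed under limma, with 355 at an unadjusted p under 0.05 and 491 (11.7%, where chance gives 10%) not overlapping. The count was 82 without dam mock replicate 3 and 5 without WT mock replicate 2, and 113 with array weights.

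In mutS against WT, 0 genes passed under limma (lowest adjusted p = 0.051), with 142 at an unadjusted p under 0.05 and 719 (17.2%, where chance gives 20% for n = 2 and 3) not overlapping with the pair averaged. cheA, the chemotaxis kinase gene, stood at 32.6 against 8.05 (log2 1.89 ± 0.351, n = 2 and 3, adjusted p = 0.0864), or 1.14-fold against the WT mock intergenic level of 28.5. Flagella and chemotaxis ranked higher, with 49 of 51 positive, 0 genes over all genes and cheA and motB adjusted over the list alone (camera adjusted p = 2.94e-12, adjusted p = 0.938 with an estimated correlation). Acid and general stress and ribosomal protein genes ranked higher and Qin and Rac genes lower with 0 genes on either count (adjusted p = 7.13e-06, 0.00417 and 0.00745, adjusted p = 0.938 with an estimated correlation for each). The count was 6, 4 and 1 without mutS mock replicates 3, 1 and 2. The stress list gave 0.959 without mutS mock replicate 3 and the ribosomal list 0.883 without WT mock replicate 3. The Qin and Rac list gave 0.905, turned higher, without mutS mock replicate 3 and 0.239 without WT mock replicate 1.

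In dam mutS against WT, 13 gene probe sets were higher and 0 lower, 11 of them below the intergenic level in both groups, with 404 at an unadjusted p under 0.05. ydiH was 3.31-fold higher (log2 1.73 ± 0.273, n = 3 and 3, adjusted p = 0.00671) and fbaB 3.11-fold (SE 0.187, adjusted p = 0.000374), or 2.69-fold and 1.56-fold against the WT mock intergenic level of 28.5, below which they lay there. The next 6 lay below the intergenic level in both groups. nirD, yfjH and bcsE, the last a gene of cellulose synthesis, were 2.76-fold, 2.69-fold and 2.36-fold higher (SE 0.233, 0.175 and 0.127, adjusted p = 0.00671 or lower). yhhY, tesA, a thioesterase gene, and sufB, a gene of iron-sulfur cluster assembly, were 2.09-fold, 2.02-fold and 1.85-fold higher (SE 0.206, 0.16 and 0.176, adjusted p = 0.0387, 0.00671 and 0.0428). recA stood at 222 against 29.8 and did not pass (7.22-fold, SE 0.675, adjusted p = 0.0973). The dam mutS mock arrays read 53.0, 524 and 388, so the mean describes none of them. Dam mutS mock replicate 1, the lowest, had WT mock replicate 1 as its nearest array (SD 1.02), and whether its label is right was not tested. Ribosomal protein genes ranked higher with 0 over all genes and 13 of 35 adjusted over the list alone (camera adjusted p = 1.23e-13, adjusted p = 0.929 with an estimated correlation). Flagella and chemotaxis and aerobic respiration ranked higher with 0 on either count (adjusted p = 0.00419 and 0.0479, adjusted p = 0.929 with an estimated correlation for both). Without dam mutS mock replicate 2 flagella gave 0.791 and without replicate 3 aerobic respiration gave 0.788. The groups did not overlap in 666 (15.9%, where chance gives 10%). The count was 94, 49 and 26 without dam mutS mock replicates 3, 1 and 2, 5 without WT mock replicate 3 and 0 with the 6 arrays alone. It was 1 with arrays centred on their brighter gene probe sets, which lowered the median of all genes by 0.287. Without WT mock replicate 3 sufB, yhhY, tesA and nirD gave adjusted p = 0.184, 0.118, 0.0605 and 0.0572.

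In dam mutS against dam, which asks what the loss of MutS adds in untreated dam cells, 7 gene probe sets were higher and 0 lower, 6 of them below the intergenic level in both groups, with 265 at an unadjusted p under 0.05. fbaB was 2.62-fold higher (log2 1.39 ± 0.187, n = 3 and 3, adjusted p = 0.00214), or 1.35-fold against the dam mock intergenic level of 33.3, below which it lay there. The next 6 lay below the intergenic level in both groups. nirD, bcsE, yfjH and tesA were 2.41-fold, 2.31-fold, 2.2-fold and 2.1-fold higher (SE 0.233, 0.127, 0.175 and 0.16, adjusted p = 0.0387 or lower). acpT, for a phosphopantetheinyl transferase, and ybbA were 1.77-fold and 1.67-fold higher (SE 0.109 and 0.142, adjusted p = 0.00214 and 0.0493). DLP12 and CP4-57 genes ranked higher with yfjH on both counts, that is over all genes and adjusted over the list alone, and acid and general stress with 0 (camera adjusted p = 0.00321 and 0.00555, adjusted p = 0.761 with an estimated correlation for both). Flagella, ribosomal protein, aerobic respiration, maltose and heat shock genes ranked lower with 0 on either count (adjusted p = 0.000118, 0.000243, 0.00302, 0.00338 and 0.00555, adjusted p = 0.761 with an estimated correlation for each). The groups did not overlap in 305 (7.28%, where chance gives 10%). The count was 62, 22 and 12 without dam mutS mock replicates 3, 2 and 1, 0 with the 6 arrays alone and 1 with arrays centred on their brighter gene probe sets. Without dam mutS mock replicate 1 the 7 lists became 1, without dam mutS mock replicate 2 acid and general stress gave 0.542, and without dam mock replicate 2 aerobic respiration turned higher (0.553). nirD and ybbA gave adjusted p = 0.171 without dam mock replicate 1.

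The other 9 lists, namely mismatch repair, the dam operon, excision repair outside the SOS regulon, envelope stress, oxidative stress, thiol and glutathione, metal efflux and uptake, iron acquisition and pyrimidine biosynthesis, ranked neither higher nor lower in any of the 11 comparisons. Their smallest adjusted p were 0.119, 0.245, 0.385, 0.0937, 0.46, 0.302, 0.303, 0.072 and 0.348. Single members passed over all genes, such as mutM, a DNA glycosylase gene, 2.11-fold higher in dam after cisplatin and below the intergenic level in both groups (SE 0.25, adjusted p = 0.0229), which lost the call without dam mock replicates 2 and 3 and dam cisplatin replicate 3 (0.0746, 0.0629 and 0.12). In the same comparison the iron superoxide dismutase gene sodB was 5.90-fold lower (SE 0.584, adjusted p = 0.0203), a call lost without 4 of the 6 arrays (up to 0.118).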

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

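The tests of sample labels, of replicate numbers, of the starting level in mock, of the spread near background and of the between-array scaling were chosen only after the result was seen, while those of the mRNA share, of a shift of low values and of other splits of the arrays were set beforehand.

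Responses to cisplatin that differed between strains by an interaction contrast stood out. In dam against WT these were yebE (3.07 in log2) and mgtA (2.51), which lay below the intergenic level in all but dam cisplatin so that the sizes depend on the background, and the lists of flagella and chemotaxis (adjusted p = 3.68e-13), maltose and carbon transport (7.24e-07), ribosomal proteins (2.31e-05), aerobic respiration (0.00219), DNA replication (0.00279), anaerobic respiration (0.0114), tryptophanase (0.0135) and the citric acid cycle (0.0342). In mutS against WT they were the tryptophanase (adjusted p = 0.000429), e14 (0.0147) and SOS (0.015) lists. In dam mutS against dam they were aerobic respiration (adjusted p = 0.000895), flagella and chemotaxis (0.00277), the citric acid cycle and DLP12 and CP4-57 prophages (0.0038 for both), maltose and carbon transport (0.0446) and nucleoid genes (0.0488). With an estimated correlation the smallest adjusted p of these lists was 0.371.

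Signal also changed after cisplatin in probe sets the comparisons of genes left out. Of 2761 intergenic probe sets with no gene, 3 were higher in WT, 18 in dam, 3 in mutS and 23 in dam mutS, and the 3 of WT were also higher in mutS and dam mutS, and 2 of them in dam. In the same order 0, 37, 0 and 14 were lower, so in dam more fell than rose. Of 313 other probe sets without a gene name here, 0 were higher in WT, 4 in dam, 0 in mutS and 2 in dam mutS under limma, and 0, 2, 0 and 8 were lower.

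The flagellar, sugar-uptake and tryptophanase lists responded lower in dam than in WT by camera alone, since with an estimated correlation the adjusted p was 0.371 for each and 0 of their genes passed over all genes. A lower share of mRNA in the RNA of the dam cisplatin arrays, where 3 of 18 ribosomal RNA probe sets rose, would lower other bright genes alike. The median log2 change of 430 bright genes outside these lists was -0.276 (-0.543 to -0.098 without 1 array), with 9 called higher and 35 lower, against -3.53 for 32 bright genes of the lists. This leaves it open, since the range passes the bound of -0.5 set beforehand and the scaling within GCRMA can hide a common fall. A higher starting level in the dam mock arrays could account for part of the difference. After cisplatin the 89 members differed between dam and WT by a median log2 of -0.159, against 0.967 in mock. This cannot decide it, since genes near the floor after cisplatin in both strains differ little whatever the cause. malE, for example, lay at 8.07 to 12.7 in dam and 9.35 to 14.9 in WT, below the intergenic levels of 33.1 and 30. How many of the 89 lay there was not counted. The flagella list still ranked lower in dam after cisplatin (median -0.154, camera adjusted p = 0.0381, 0.722 with an estimated correlation). For the 3 tryptophanase genes the median after cisplatin was -3.35 (-4.57 to -2.32 without 1 array), which the starting level alone would not give. These genes have adjacent locus tags (b3707 to b3709), and tnaA did not pass between dam and WT there (log2 -3.65, SE 1.15, limma adjusted p = 0.163). For these 3 genes the values thus argue against the starting level as the only cause, within that limit, while a part of it in the difference stays open. Whether the higher mock level stems from the dam mutation or from the growth of those cultures was not tested.

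Of the 24 arrays 16 had their nearest array in another strain, all of the same treatment, so strains overlapped in general. Dam mutS cisplatin replicate 1 was among them, and lay nearer to the dam cisplatin arrays than to its own group. A swap with one of them would leave a dam cisplatin array nearer to dam mutS cisplatin replicates 2 and 3, and 0 were (1.49 against 1.04, 1.06 against 0.753 and 1.15 against 0.755), which argues against it. Handling shared by arrays of 1 replicate number stays open. This array and dam cisplatin replicate 1 were nearest to each other (SD 0.662), and their r of 0.530 was the highest of 84 pairs of equal number. The dam cisplatin arrays of other numbers, at 1.15 and 1.11, were also nearer than its own group, which such handling does not predict. A single wrong label could give its mean SD of 0.973 to the dam cisplatin arrays against 1.52 to its own group, and so could a stronger response of that culture. The 7 genes that separate the strains in mock do not tell them apart, since their mean log2 was 3.12 there, 3.03 to 3.24 in dam cisplatin and 3.13 in its own group.

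In dam mutS mock against WT, 11 of the 13 genes called higher lay at background level. An upward shift of all low values is argued against by the intergenic probe sets, with a median log2 difference of -0.102. Between-array scaling stays open, since centring lowers each gene alike, by 0.287, and so decides nothing about these 13. With it the median log2 went from 1.01 to 0.727 and the SE from 0.16 to 0.221, all 13 stayed above 0 and 1 kept its call, as the differences shrank and the SE grew. A small spread of values near background was left open, since 0.31% of gene and 0.109% of intergenic probe sets were called higher (two-sided Fisher's exact p = 0.123). The 13 genes were also among the 40 lower after cisplatin in dam mutS, which is no independent evidence, since both comparisons use the same mock arrays. A strain difference stays open as the biological explanation and was not tested.

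Other splits of the same arrays were counted for each comparison with 3 arrays per group, and the mutS comparisons were left out because of the averaged pairs. With 10 splits, too few for a share under 0.05, the real count and the highest other were 8 and 0 for cisplatin in WT, 158 and 0 in dam, 70 and 20 in dam mutS, 0 and 4 for dam against WT in mock, 13 and 44 for dam mutS against WT in mock and 7 and 158 for dam mutS against dam in mock. The splits with as many as the real one, itself included, were 1, 1, 1, 10, 2 and 5, the 10 following from a real count of 0. The 158 and 44 point to a structure of the mock arrays that the strains do not explain, where dam mock replicate 1 and dam mutS mock replicate 2 were nearest to each other (SD 0.678). For the difference of response between dam and WT 6 of 100 splits gave 2 or more genes (highest 34), so chance was not excluded, and for dam mutS against dam the real count of 0 is matched by 100 of 100 by construction and says nothing on chance. The highest other count of 108 there also points to a structure of the arrays.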

How the results depend on the processing

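Averaging the near-identical pairs, keeping 24 arrays separate, averaging dam cisplatin replicates 2 and 3 as well and testing only genes above the intergenic level were chosen only after the result was seen, and the other alternatives were set beforehand. No named gene reversed under any alternative, and 22 of the 125 named calls held under all of them and 79 without each array in turn, while 1 of 83 list calls held under all and 33 without each array. The counts of called genes moved as follows, and where a cause is not given by fewer arrays or fewer genes the cause was not tested. With the arrays of the groups compared alone they were 1 in WT, 52 in dam, 0 in mutS, 2 in dam mutS, 0 for dam mutS against WT and against dam in mock and 13 for the difference between dam and WT. With array weights they were 72 in WT, 304 in dam, 39 in dam mutS, 113 for dam, 1 for mutS and 40 for dam mutS against WT in mock, and 106, 2 and 3 for the differences of dam and WT, mutS and WT, and dam mutS and dam. With arrays centred on their brighter gene probe sets they were 9 for dam and 1 for dam mutS against WT in mock, 1 for dam mutS against dam in mock and 1 for the difference of dam and WT. Centring moved the median of all genes by 0.173 in mutS and 0.15 in dam mutS after cisplatin, by -0.194, -0.281 and -0.287 for dam, mutS and dam mutS against WT in mock and by 0.13 for the difference of mutS and WT. With a pseudocount of 16 they were 3 for mutS against WT in mock and 1, 1 and 10 for the 3 differences, and the split was 7 higher and 0 lower in WT (100% higher against 87.5%) and 10 and 4 in mutS (71.4% against 83.3%). With all probe sets that are not controls, where those without a gene are counted too, they were 118 in dam mutS, 20 for dam mutS against WT in mock and 0 for the difference of dam and WT. Of the 118, 23 higher and 14 lower were intergenic with no gene, and 2 higher and 8 lower were other probe sets without a gene name. Of the 20, 13 were gene probe sets. Without the dimmest 25% they were 9 for dam and 6 for dam mutS against WT in mock, and with an intensity trend 2 for the difference of dam mutS and dam. With the replicate number as a block they were 1 for mutS and 8 for dam mutS against WT in mock and 0 for the difference of dam and WT, but the numbers do not pair the samples (r over 0.1 in 28 of 84 pairs of equal number, median 0.0182). With 24 arrays kept separate they were 19 in mutS, 8 for dam and 1 for mutS against WT in mock, 12 for dam mutS against dam in mock and 14, 1 and 5 for the 3 differences. With dam cisplatin replicates 2 and 3 averaged as well they were 104 in dam and 0 for the difference of dam and WT. Among genes above the intergenic level in at least 1 group they were 44 in dam mutS, 52 for dam and 2 for dam mutS against WT in mock, 0 for dam mutS against dam in mock and 5 for the difference of dam and WT.

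Without 1 array the counts ranged from 7 to 8 in WT, 91 to 201 in dam, 11 to 23 in mutS and 63 to 189 in dam mutS, from 0 to 82, 0 to 6 and 5 to 94 for dam, mutS and dam mutS against WT in mock, from 6 to 62 for dam mutS against dam in mock, and from 0 to 31, 0 to 3 and 0 to 47 for the 3 differences. Called lists numbered 7 in WT, 13 in dam, 8 in mutS, 15 in dam mutS, 9, 4, 3 and 7 in the 4 mock comparisons and 8, 3 and 6 for the differences. With an estimated correlation these were 1, 0, 2, 0, 0, 0, 0, 0, 0, 0 and 0, and with fry 0, 10, 1, 11, 0, 0, 0, 0, 0, 0 and 0. With centring they were 8 for mutS against WT in mock and 7 for the difference of mutS and WT, which was also 7 with the block and 5 with a pseudocount of 16. Without 1 array they ranged from 5 to 9, 10 to 14, 6 to 8 and 8 to 15 after cisplatin, 6 to 9, 3 to 7, 2 to 5 and 1 to 8 in mock and 6 to 12, 1 to 8 and 2 to 8 for the differences. Each of 5 lists reversed, with no call, without 1 array. In mutS after cisplatin, without mutS mock replicate 3, these were the citric acid cycle (adjusted p = 0.88, range without 1 array 0.00572 to 0.88) and Qin and Rac (0.955, range 0.00974 to 0.955). In dam mutS after cisplatin it was the ribosomal list without dam mutS mock replicate 1 (0.847, range 8.86e-05 to 0.905). In mock they were Qin and Rac for mutS against WT without mutS mock replicate 3 (0.905, range 0.000575 to 0.905) and aerobic respiration for dam mutS against dam without dam mock replicate 2 (0.553, range 2.04e-09 to 0.624). Across the brighter gene probe sets r was 0.471 for WT and dam mutS, 0.3 for dam and mutS and 0.394 for mutS and dam mutS. Without 1 array r ranged from 0.284 to 0.449 for WT and dam, 0.347 to 0.625 for WT and mutS, 0.268 to 0.443 for WT and dam mutS, 0.217 to 0.282 for dam and mutS, 0.484 to 0.748 for dam and dam mutS and 0.24 to 0.395 for mutS and dam mutS. Only 10.6 to 24.2% of gene probe sets lay above the intergenic level of an array, which limits what can be seen in the others.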

Other observations

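The comparisons of strains within cisplatin and of dam mutS with mutS in mock were chosen only after the results were seen. After cisplatin, dam cells had more transcript than WT of gyrA (5.77-fold), gyrB (4.04-fold) and uvrA (3.84-fold; SE 0.394, 0.305 and 0.404 in log2, n = 3 and 3, adjusted p under limma 0.00267, 0.00234 and 0.0233). In WT gyrB and uvrA lay below the intergenic level of 30, against which dam had 3.44-fold and 1.25-fold more. yjcB, yhcN, yebE, bhsA, tsuB and deaD were 10.8-fold, 10.1-fold, 9.38-fold, 9.15-fold, 8.99-fold and 8.23-fold higher, deaD at 784 against 94.4. The first 5 lay below the intergenic level in WT, against which dam had 3.03-fold, 3.71-fold, 1.92-fold, 3.65-fold and 4.87-fold more, all less than deaD. grcA, fimA and yobF were 12.7-fold, 6.87-fold and 4.82-fold lower in dam than in WT (adjusted p = 0.0046, 0.0143 and 0.0394). In total 49 probe sets were higher and 3 lower, 22 of their 51 genes below the intergenic level in both groups, and the count was 26 without WT cisplatin replicate 2 and 109 without dam cisplatin replicate 1. By camera 12 lists passed, and with an estimated correlation 0 did (lowest adjusted p = 0.278). Ribosomal proteins ranked higher in dam (adjusted p = 1.51e-06, median log2 1.31, 33 of 35 above 0) with 0 genes called, as did SOS and DNA replication (0.000116 for both) with 1 of 31, uvrA, and 7 of 21. Sulfate assimilation, thiol and glutathione, ribonucleotide reduction and purine biosynthesis also ranked higher (0.012, 0.0381, 0.0426 and 0.0426). Qin and Rac, acid and general stress, flagella and chemotaxis, tryptophanase, and DLP12 and CP4-57 ranked lower (0.00277, 0.0282, 0.0381, 0.0426 and 0.0426). Ribosomal, SOS, DNA replication and Qin and Rac lists held without each array, and the others lost the call without 1 to 4 of the 6. Without dam cisplatin replicate 1 sulfate, stress, thiol and flagella gave 0.123 each, tryptophanase 0.133, purine 0.159 and ribonucleotide reduction 0.296, and without dam cisplatin replicate 2 DLP12 and CP4-57 gave 0.111.

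In dam mutS against dam after cisplatin, 1 gene was higher and 9 were lower, 8 of the 10 below the intergenic level in both groups, yebE 4.84-fold lower (SE 0.358, adjusted p = 0.0134) and rsmG 3.15-fold lower (SE 0.303, adjusted p = 0.0298), or 1.65-fold and 1.13-fold against the dam mutS intergenic level of 35.0, below which both lay there. The count was 3 without dam cisplatin replicate 3 and 162 without dam mutS cisplatin replicate 1. By camera ribosomal proteins and DNA replication ranked lower (adjusted p = 0.00658 and 0.0177) and the citric acid cycle and acid stress higher (0.00658 and 0.0177), with 0.808 for each with an estimated correlation. Each lost the call without at least 3 of the 6 arrays, reaching 0.422 and 0.123 without dam mutS cisplatin replicate 3 and dam cisplatin replicate 1, and 0.144 and 0.206 without dam mutS cisplatin replicate 2. In mutS against WT after cisplatin, phnI and ydfE were 1.86-fold and 1.56-fold higher at background level (adjusted p = 0.000612 and 0.0439), with 16 genes without mutS cisplatin replicate 1 and 1 without mutS cisplatin replicate 2. Flagella, SOS, maltose, tryptophanase and acid stress lists ranked higher (3.11e-06, 8.36e-05, 0.000354, 0.00178 and 0.0159, with 0 genes called and 0.915 or more with an estimated correlation). Without mutS cisplatin replicate 1 flagella gave 0.0587 and maltose and tryptophanase 0.108, and without WT cisplatin replicates 1 and 2 acid stress gave 0.0768 and 0.202. In dam mutS against mutS in mock, 4 genes were higher, nirD, yfjH, bcsE and acpT, and yciG was lower, all 5 below the intergenic level in both groups, with 21 genes without dam mutS mock replicate 3. Ribosomal and DLP12 and CP4-57 lists ranked higher and acid stress lower (9.3e-07, 0.0345 and 0.00963, 0.89 with an estimated correlation). Each lost the call without at least 2 of the 6 arrays. Without mutS mock replicate 3 ribosomal and stress genes gave 0.804, the latter turned higher, and without dam mutS mock replicate 1 DLP12 and CP4-57 gave 0.914.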
